A study of Mus musculus with 7 samples.

How the data were processed

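Total RNA of whole liver taken 12 h after PHx was labelled with biotin and hybridised to single-colour Illumina bead arrays, per the labels. The 7 samples comprised 4 KO and 3 WT samples by the genotype in their labels, with replicate numbers from their titles. The labels do not say outright that each sample came from a separate animal, so p-values measure the spread between these samples, which may in part be technical. The deposited values were linear intensities per probe that the authors had normalized between arrays. The quantiles of the 7 columns coincided, and no background had been subtracted as far as the values show. The submitters' processing notes name Partek, with its version not given in the sources used here. Each array's deposited intensities had a median of 91.1. A table of scanner output, with 7 signal and 7 detection p columns named by chip and position, was not used, because the labels tie none of these 14 columns to a sample.

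The plan fixed before the data were examined had been to start from the scanner table, with detection p as the filter and slide as a block. It was replaced as follows. The deposited intensities were background-corrected by normexp (saddle-point fit, offset 16) with limma 3.58.1 in R 4.3.3 and put on the log2 scale. The floor was the upper bound of the background, at an intensity of 91.3 (4.88 on the corrected log2 scale). It was taken as the 0.95 quantile of a normal curve fitted to the lower side of the most frequent intensity. Probes above the floor on at least 3 arrays were kept, 23485 of 45281. Of all probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. RefSeq of GRCm38.p6 matched 34807 probes by Entrez identifier and changed 0 symbols. This table was used for names and for the order of genes along a chromosome. For the 4695 genes with several kept probes, the brightest was used. Probes with no symbol or several were tested under their own identifiers, 3935 in all. Genes with close paralogs, such as Mug2, Mug-ps1 and Mug1, can share signal with them, and probe sequences were not used here.

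KO was compared with WT by lmFit and eBayes of limma (default prior, no covariates), with Benjamini-Hochberg adjustment over 16422 genes or unnamed probes and a two-sided adjusted p under 0.05. All log2 differences are KO minus WT. The 37 lists, 25 of genes and 12 of cell type markers, were fixed before the data were examined. Each list's members were adjusted among themselves ("adjusted over the list alone"), and lists with at least 5 measured genes were tested by camera (preset correlation 0.01), by camera with an estimated correlation, and by fry. Adjusted p of lists are over the 37 lists.

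Named genes followed a rule fixed before the data were examined. It took Ltbr and Tnfrsf1a, and up to 12 higher and 12 lower genes past the threshold, with a single symbol and groups that do not overlap, by size. Where fewer passed, the genes of smallest p filled a direction up to 6, as values only. It also took up to 4 members of smallest p from each list, a fixed set of regeneration genes, and any called gene whose probes differ in direction. Not all genes it allowed are printed.

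The lists without further description were lymphoid tissue chemokines, NRF2 targets, heat shock proteins, MHC and antigen presentation, circadian clock genes and male-biased and female-biased liver genes. Further cell type markers were those of monocytes and dendritic cells, neutrophils, T and NK cells, B and plasma cells, sinusoidal endothelium, stellate cells and fibroblasts, cholangiocytes, erythroid cells and pancreas.

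The procedure was tested on simulated data made from the means and spreads of the 16422 genes for the comparison of KO with WT, with 200 genes changed. It recovered 14 of 67 genes changed by 1.5-fold, 56 of 67 changed by 2-fold and 66 of 66 changed by 4-fold, with 12 calls among unchanged genes. A list of 30 genes shifted by 0.3 had a camera p of 1.0e-12, and 0.00047 with an estimated correlation. Simulated genes varied independently of each other, whereas the estimated correlation was 0.29 for the macrophage markers in the real data. The simulation therefore does not show how the tests perform on correlated genes. Sample correlations over the genes tested were 0.969 to 0.987 within groups and 0.964 to 0.979 between them. The first principal component held 29.6% of the variance and the second 25.2%.

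Alternatives changed the background correction, the normalization, the filter, the choice of probe, the eBayes prior, array weights, the threshold and the replicate block, and left out each sample in turn. A further alternative leaving out KO replicate 3 and WT replicate 3 together was chosen after seeing the data.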

Results

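Gene expression was measured in whole mouse liver 12 h after partial hepatectomy (PHx), the surgical removal of part of the liver that makes the remaining tissue regenerate. The arrays were single-colour Illumina bead arrays, 1 per sample, of C57BL/6 mice. They comprised 4 samples of mice deficient in the lymphotoxin beta receptor (LTBR; KO) and 3 samples of wild-type mice (WT). The comparison of KO with WT asked how gene expression in regenerating liver differed with loss of this receptor of the tumour necrosis factor (TNF) receptor family. All samples were taken after PHx. A difference present before the operation cannot be told apart from one that arose during regeneration. The deposited intensities ran from 72.6 to 30878 on every array, with a median of 91.1, and 22301 of the 45281 probes lay above an intensity floor of 91.3. After filtering, 16422 genes or unnamed probes were tested, 12487 of them with a gene symbol. The number of arrays limits the precision, and the median standard error (SE) of a log2 difference was 0.18.

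The targeted gene Ltbr was measured by 1 probe and was lower in each of the 4 KO samples than in each of the 3 WT samples. Its log2 intensity was 6.63, 7.04 and 7.28 in WT and 5.86, 6.23, 6.08 and 5.61 in KO. The log2 difference of -1.04 (SE 0.20), 2.05-fold, had an adjusted p of 0.083 and so missed the threshold. The place of this probe relative to the deleted part of the gene was not given in the sources used here. Tnfrsf1a, the gene of TNF receptor p55, lies 2 tested genes from Ltbr on chromosome 6. Its log2 intensity was 6.78 ± 0.33 (SD, n = 3) in WT and 6.08 ± 0.12 (SD, n = 4) in KO. The log2 difference of -0.70 (SE 0.18) had an adjusted p of 0.13, and its 3 probes gave differences between -0.72 and -0.55.

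A total of 12 genes or unnamed probes differed between KO and WT at an adjusted p under 0.05, 3 higher and 9 lower in KO. Murinoglobulin 2 (Mug2), a plasma protease inhibitor made by hepatocytes, fell from a log2 intensity of 12.53 ± 0.17 (SD, n = 3) in WT to 7.80 ± 0.69 (SD, n = 4) in KO, 26.6-fold (adjusted p = 2.0e-05). The related pseudogene Mug-ps1 fell from 8.56 ± 0.28 (SD, n = 3) to 4.94 ± 0.21 (SD, n = 4), close to the floor of 4.88, or 12.3-fold (adjusted p = 2.2e-06). Pdgfa, a chain of platelet-derived growth factor, rose by 1.28 on the log2 scale (SE 0.17, adjusted p = 0.036). Rabgap1, which acts on Rab GTPases, passed only at its brightest probe, which rose by 0.95 (SE 0.15, adjusted p = 0.048). Its 4 other kept probes lay between -0.25 and 0.21, and the mean of its kept probes differed by 0.17 (adjusted p = 0.70, the highest over all settings, the lowest being 0.012).

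The other 5 named genes past the threshold were lower in KO by 2.11-fold to 2.80-fold, with adjusted p between 0.036 and 0.038. They were Eef2, translation elongation factor 2 (log2 difference -1.48, SE 0.22), and Tmprss6, a membrane serine protease that restrains hepcidin (-1.28, SE 0.19). The others were Afmid, an enzyme of tryptophan breakdown (-1.17, SE 0.16), Ptms, which encodes parathymosin (-1.13, SE 0.16), and Albfm1 (-1.08, SE 0.15). The remaining 3 calls were probes without a gene symbol. All 12 had 4 KO values on one side of the 3 WT values, as did 11.6% of the genes tested, against 5.71% by chance. All kept probes of Eef2 (3), Tmprss6 (2), Afmid (7) and Ptms (2) lay below 0. Probes other than the brightest gave smaller differences for Afmid (-0.92 to -0.11), Ptms (-0.75) and Tmprss6 (-0.70). For Eef2 they were slightly larger (-1.59 and -1.51). The next genes by p with a higher KO mean did not pass. These were Serpinb6b (1.78, SE 0.29, adjusted p = 0.055), S100a11 (1.15, SE 0.20), Armcx1 (0.84, SE 0.15) and Sltm (1.05, SE 0.19). Without KO replicate 3, Serpinb6b (2.03), S100a11 (1.22) and Sltm (1.13) passed, Sltm at its brightest probe only, since its 3 other kept probes lay between -0.04 and 0.03 with all arrays. Of the 80 genes named, 32 had further kept probes, and for 8 at least 1 of these had the opposite sign. Besides Rabgap1 and Sltm these were Irf1 (further probes from -0.07 to 0.44), Cdk2 (-0.16 to 0.49), Vcam1 (-0.25 to 0.40), Tgfbr1 (-0.13 to 0.46), Acss2 (0.07) and Saa1 (-0.11).

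Mug2 and Mug-ps1 passed the threshold with each of the 7 arrays left out in turn, and the other calls did not. Without WT replicate 1, 4 genes passed, and 2 passed without WT replicate 2 and without KO replicates 1, 2 or 4. Without WT replicate 3, 16 passed, 5 of them among the 12. Without KO replicate 3, 35 passed, and without both KO replicate 3 and WT replicate 3, a choice made after seeing the data, 592 passed. With those arrays left out, genotype coincides with another division of the arrays, WT replicates 1 and 2 with KO replicate 3 against the rest. The 592 thus cannot be assigned to genotype alone. At an unadjusted p under 0.05 there were 2131 genes, 13.0% of those tested, where 5% are expected if no gene differs. The split of WT replicates 1 and 2 with KO replicate 3 from the other arrays gave 2150.

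**Figure D1:**
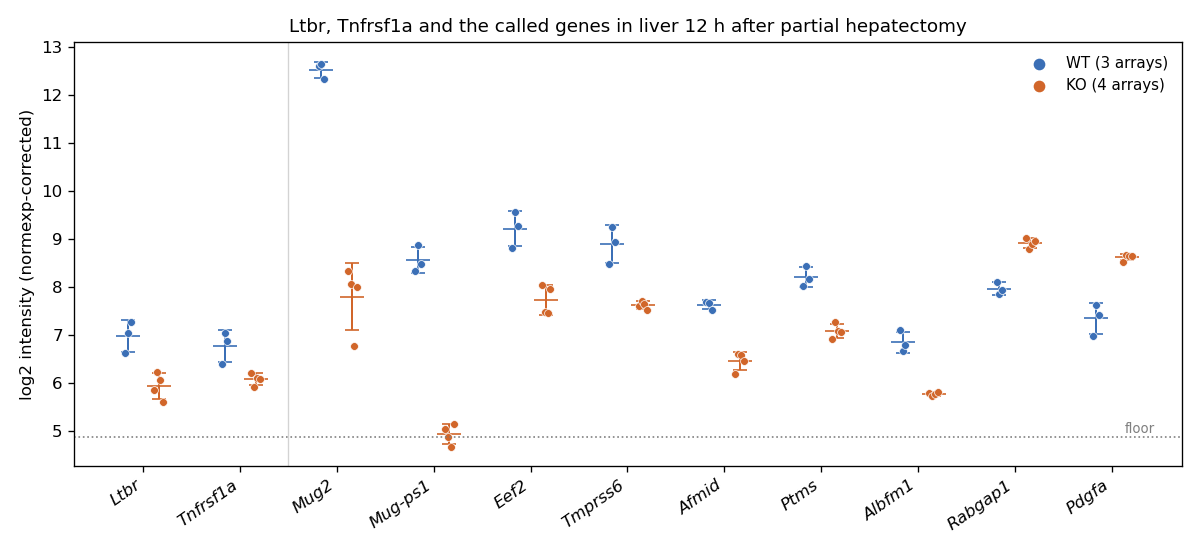
Log2 intensity (y axis, normexp-corrected) of Ltbr, Tnfrsf1a and the 9 named genes past the threshold (x axis) in 3 WT and 4 KO samples. Points are arrays, wide dashes are group means and bars are SDs. Mug2 lies at 12.53 in WT and 7.80 in KO, and Mug-ps1 in KO lies close to the floor of 4.88 drawn as a dotted line.

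Mug2, Mug-ps1 and Ptms lie on chromosome 6, within 50 tested genes of Ltbr. Of the 59 measured genes in a list of distal chromosome 6 genes near Ltbr, drawn up without Ltbr itself, Mug2 and Ptms fell and none rose. This was 3.39% of the list against 0.061% of the other genes (10 of 16362; one-sided Fisher's exact test, p = 0.00082). Mug-ps1 was not on the list. Neither was A2ml1, an alpha-2-macroglobulin-like gene chosen after its value was seen, which lies 21 tested genes from Ltbr on the side away from Mug2, Mug-ps1 and Ptms. It differed by -2.02 (SE 0.32, adjusted p = 0.052), with -2.09 at its other probe, and passed without WT replicate 3 (-2.32, adjusted p = 0.039) or KO replicate 3 (-1.77, adjusted p = 0.044). Adjusted over the list alone, 6 members were lower and 1 higher in KO, among them Fkbp4, which encodes an immunophilin (-0.74, SE 0.16), Tnfrsf1a, and the RNA-editing enzyme gene Apobec1 (1.10, SE 0.25, or 1.43 and past the threshold over all genes without WT replicate 3). The list did not pass in 1 direction (median -0.03, adjusted p = 0.19 by camera), with 31 members below 0 and 28 above. In fry's test for change in either direction, which does not compare a list with other genes, it had the lowest p of the 37 lists (adjusted p = 5.1e-05). The list holds the called genes Mug2 and Ptms and was not tested without them. That p is thus not separate from their calls.

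**Figure D2:**
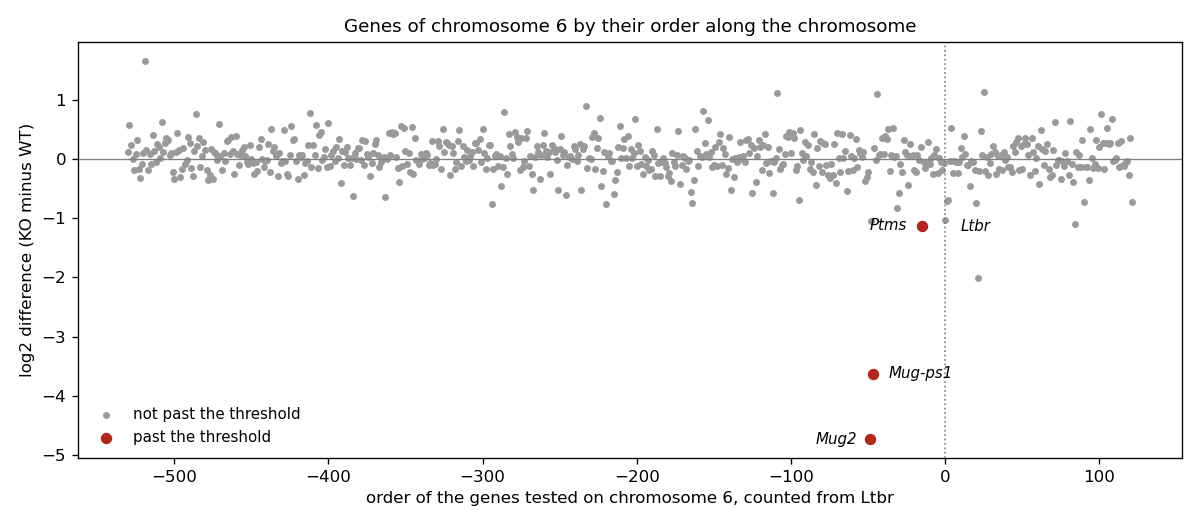
Log2 difference between KO and WT (y axis) of the 652 genes tested on chromosome 6, in their order along the chromosome counted from Ltbr (x axis, number of genes). Each point is a gene, and the larger red points are the 3 genes past the threshold, Mug2 at -4.73, Mug-ps1 at -3.62 and Ptms at -1.13. A2ml1 at -2.02, on the other side of Ltbr, narrowly missed the threshold.

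NF-kB target genes, which LTBR and TNF receptors can activate, were higher in KO as a list. Of 24 measured members 17 lay above 0, with a median log2 difference of 0.19 (adjusted p = 0.0091 by camera with a preset correlation). The call was lost when the correlation was estimated (adjusted p = 0.46 with an estimated correlation). No member passed over all genes tested, and 4 were higher adjusted over the list alone. They were the transcription factor gene Irf1 (1.0, SE 0.20), Tnip1, which encodes a partner of the NF-kB inhibitor A20 (0.79, SE 0.21), the adhesion molecule gene Vcam1 (0.62, SE 0.17) and the survival gene Bcl2a1d (0.52, SE 0.16). Icam1 (-0.08, SE 0.21), Relb (0.35, SE 0.19) and Nfkb2 (-0.01, SE 0.16) did not pass. The list score of KO replicate 4 was 0.42 against -0.00 to 0.03 in the other KO samples. The list no longer passed without KO replicate 4 (median 0.11, adjusted p = 0.14) or without WT replicate 2 (median 0.09, adjusted p = 0.098), and its median was 0.37 without WT replicate 3 (adjusted p = 0.0038).

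Markers of Kupffer cells and macrophages were also higher in KO, 17 of 19 lying above 0 with a median of 0.31 (adjusted p = 0.0011 by camera; adjusted p = 0.46 with an estimated correlation). No marker passed over all genes, and the scavenger receptor gene Marco (1.71, SE 0.34) was higher adjusted over the list alone. Vsig4, a complement receptor of tissue macrophages, differed by 0.75 (SE 0.24). The values were 0.52 (SE 0.17) for the haemoglobin scavenger receptor gene Cd163 and 0.58 (SE 0.24, or 0.35 without WT replicate 3) for Ctss, which encodes cathepsin S. Cd163 is also on the list of distal chromosome 6 genes near Ltbr. The lowest score was that of WT replicate 3, at -0.56. Without it the median was 0.13 and the list did not pass (adjusted p = 0.22), and without WT replicate 1 the median was 0.56 (adjusted p = 1.2e-05).

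Several lists of hepatocyte metabolism were lower in KO. Glucose and amino acid metabolism had 26 of 32 members below 0 and a median of -0.26 (adjusted p = 0.00072 by camera; adjusted p = 0.35 with an estimated correlation). None of its members passed over all genes or adjusted over the list alone. Gys2, liver glycogen synthase, differed by -0.72 (SE 0.19), the tyrosine-degrading enzyme gene Hpd by -0.74 (SE 0.22), liver glycogen phosphorylase Pygl by -0.51 (SE 0.16), and the transaminase gene Gpt2 by 0.73 (SE 0.22, or 0.47 without WT replicate 1). Drug metabolism had 35 of 45 members below 0 and a median of -0.17 (adjusted p = 0.0013; adjusted p = 0.27 with an estimated correlation), with none passing over all genes or adjusted over the list alone. Its members of smallest p were the bilirubin-conjugating enzyme gene Ugt1a1 (-1.09, SE 0.30), Fmo1 (-0.63, SE 0.19), Ugt2b34 (-0.59, SE 0.19) and Cyp2c55 (-1.02, SE 0.34, or -0.50 without WT replicate 1). The median of the drug metabolism list was -0.28 without KO replicate 3 (adjusted p = 0.00071). The hepatocyte markers had a median of -0.08, 15 of 19 lying below 0 (adjusted p = 0.11), and none passed adjusted over the list alone.

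Bile acid synthesis and transport had 22 of 32 members below 0 and a median of -0.22 (adjusted p = 0.011; adjusted p = 0.39 with an estimated correlation). None passed over all genes. Adjusted over the list alone, the bile salt export pump gene Abcb11 (-0.74, SE 0.19) and the organic anion transporter gene Slco1a4 (-1.11, SE 0.29, or -0.71 without WT replicate 1) were lower, and Slco2b1, another such transporter gene, was higher (0.84, SE 0.19). The bile acid uptake carrier gene Slc10a1 differed by -0.22 (SE 0.19), and the sterol hydroxylase gene Cyp8b1 by -1.13 (SE 0.42, or -0.64 without KO replicate 4). Cyp7a1 was above the floor on only 2 arrays and was not tested. The list did not pass without WT replicate 2 (median -0.11, adjusted p = 0.053), WT replicate 3 (adjusted p = 0.070) or KO replicate 3 (adjusted p = 0.081).

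Lipogenesis had 13 of 21 members below 0 and a median of -0.20 (adjusted p = 0.0091; adjusted p = 0.45 with an estimated correlation). None passed over all genes, and 5 were lower adjusted over the list alone. These included Lpin1 (-0.75, SE 0.20), Acss2 (-0.73, SE 0.22), fatty acid synthase Fasn (-0.57, SE 0.18) and liver pyruvate kinase Pklr (-0.51, SE 0.16). The fifth, Thrsp (-1.75, SE 0.58, or -1.13 without WT replicate 3), was chosen after its value was seen. At their 1 other kept probe the differences were smaller, -0.46 for Thrsp and -0.16 for Pklr. The list did not pass without WT replicate 3 (adjusted p = 0.072) or KO replicate 3 (adjusted p = 0.13). Cholesterol synthesis did not pass (median -0.09, adjusted p = 0.10), with Tm7sf2 (-1.0, SE 0.21, or -1.18 and past the threshold over all genes without KO replicate 3), Nsdhl (-0.68, SE 0.18) and Ebp (-0.58, SE 0.16), all genes of late sterol synthesis, lower adjusted over the list alone. Fatty acid oxidation and PPAR-alpha targets did not pass either (median -0.11, adjusted p = 0.41). The hormone gene Fgf21 (1.53, SE 0.31) was higher adjusted over that list alone.

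The unfolded protein response and ATF4 targets had 18 of 30 members below 0 and a median of -0.11 (adjusted p = 0.016; adjusted p = 0.27 with an estimated correlation). None passed over all genes. The chaperone genes Calr (-1.15, SE 0.24) and Hyou1 (-1.09, SE 0.23) were lower adjusted over the list alone, and Creld2 (-0.69, SE 0.23) and Pdia4 (-0.63, SE 0.22), which also act in the endoplasmic reticulum, were not past it. The list did not pass without KO replicate 3 (median -0.17, adjusted p = 0.051). Its median was -0.21 without WT replicate 3 (adjusted p = 0.036) and -0.17 without KO replicate 4 (adjusted p = 0.048). Markers of adipocytes and mesothelium were lower in KO, with all 7 measured members below 0 and a median of -0.29 (adjusted p = 0.0091; adjusted p = 0.27 with an estimated correlation). No member passed over all genes, and Car3 (-1.10, SE 0.30), a carbonic anhydrase gene that hepatocytes also express, was lower adjusted over the list alone. Adiponectin (Adipoq, -0.72, SE 0.34, or -0.18 without WT replicate 3), leptin (Lep, -0.35, SE 0.16) and Upk3b (-0.29, SE 0.18) were dim and did not pass. Without KO replicate 3 the adjusted p was 0.051.

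**Figure D3:**
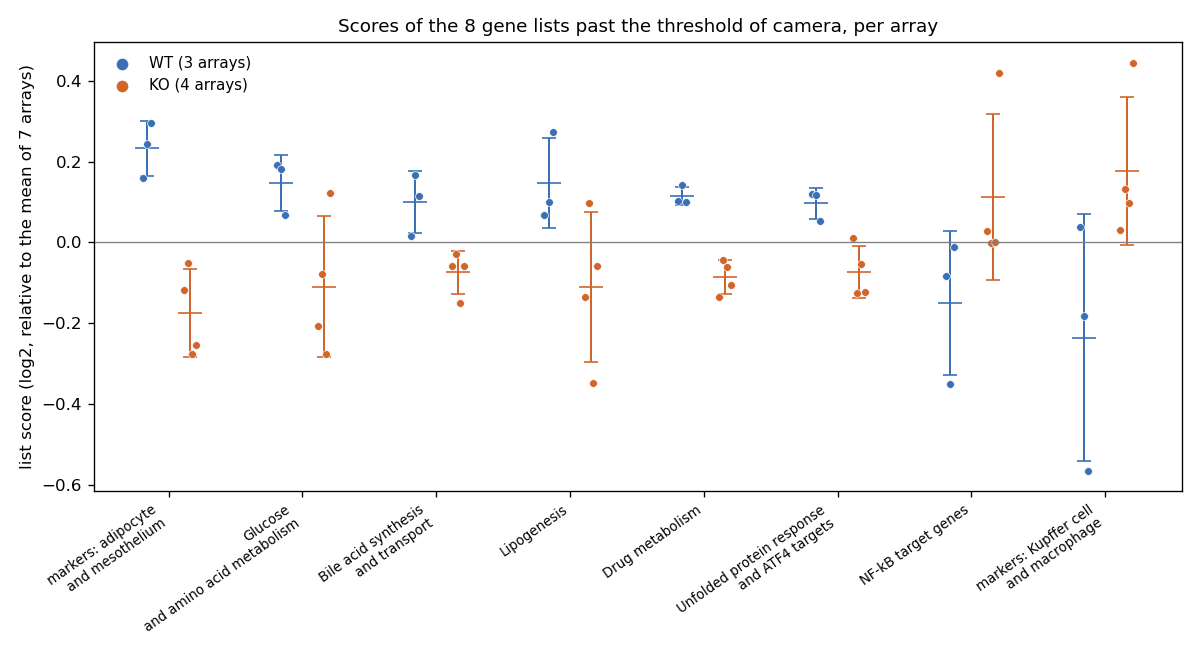
Scores of the 8 lists past the threshold of camera (x axis) in 3 WT and 4 KO samples. A score (y axis, log2) is the mean over a list's genes of the log2 intensity minus the mean over 7 arrays. Points are arrays, wide dashes are group means and bars are SDs. The macrophage score of WT replicate 3 lies at -0.56 and the NF-kB score of KO replicate 4 at 0.42.

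Genes of cell division did not pass as lists by camera, but did in fry's test for change in either direction. That test does not compare a list with other genes, and 13.0% of all genes tested had an unadjusted p under 0.05. By that measure 5 members were higher and 2 lower of 36 for G1/S, and 1 higher and 2 lower of 25 for G2/M. The passes of fry thus do not set these lists apart from other genes. The G1/S and DNA replication list had a median of 0.03 over 36 members (adjusted p = 0.95 by camera, 0.0055 by fry in either direction), and Cdk2 (0.71, SE 0.16) was higher adjusted over the list alone. The G2/M and mitosis list had a median of 0.05 over 25 members (adjusted p = 0.97 by camera, 0.038 by fry in either direction), with no member past the threshold adjusted over the list alone. Cyclin D1 (Ccnd1) differed by -0.58 (SE 0.26, or -0.34 without KO replicate 1), cyclin E1 (Ccne1) by -0.02 (SE 0.19) and the mitotic regulator Foxm1 by -0.06 (SE 0.18). Ccna2 was above the floor on 0 arrays, and Mki67 was not analysed here. Among p53 targets and CDK inhibitors (median 0.01, adjusted p = 0.81), Gadd45a (-0.77, SE 0.19) was lower adjusted over the list alone, and Cdkn1a differed by -0.17 (SE 0.17). Among growth factors and receptors of regeneration (median -0.03, adjusted p = 0.97), Fgf21 and Tgfbr1 (0.63, SE 0.16) were higher adjusted over the list alone. Hgf, the hepatocyte growth factor gene, differed by -0.14 (SE 0.38).

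Immediate early genes had a median of 0.02 (adjusted p = 0.81 by camera, as for the lists that follow), with values of 0.17 (SE 0.19) for Myc, -0.18 (SE 0.19) for Jun, 0.55 (SE 0.44, or 0.02 without KO replicate 4) for Fos and -0.35 (SE 0.41) for Igfbp1, none of which passed. Acute phase and STAT3 targets had a median of -0.06 (adjusted p = 0.30). The interleukin 6 receptor gene Il6ra (-0.90, SE 0.17, or -1.02 and past the threshold over all genes without KO replicate 3) was lower adjusted over that list alone. These values are of its brightest probe, and its 2 other kept probes differed by only -0.15 and -0.12. Socs3 (0.31, SE 0.31), Saa1 (0.34, SE 0.57) and Lcn2 (0.31, SE 0.26) did not pass. The LT and TNF receptor signalling list did not pass (median 0.15, adjusted p = 0.54), with Tnfrsf1a lower adjusted over the list alone. Among apoptosis regulators (median 0.22, adjusted p = 0.11), Casp1 (0.75, SE 0.19) was higher and Bcl2l1 (-0.70, SE 0.18) lower adjusted over the list alone. The 2 other kept probes of Bcl2l1 differed by only -0.15 and -0.02. The interferon response list did not pass (median -0.02, adjusted p = 0.83), and Irf1 was its only member past the threshold adjusted over the list alone.

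Of the 37 lists, 8 passed with the preset correlation of 0.01, 2 higher and 6 lower, and none with an estimated correlation, where the lowest adjusted p was 0.27 and 4 lists had an unadjusted p under 0.05. Without KO replicate 3, 4 passed with the preset correlation. With fry, which asks whether a list's genes move one way on balance, only the adipocyte and mesothelium markers passed (adjusted p = 0.042). Its test for change in either direction, which does not compare a list with other genes, passed 16 lists, 5 of them among the 8. Those 5 were bile acid synthesis, the unfolded protein response, NF-kB targets, glucose and amino acid metabolism, and lipogenesis. The other 11 were distal chromosome 6 genes, LT and TNF receptor signalling, erythroid, B cell and pancreas markers, both lists of cell division, cholesterol synthesis, apoptosis regulators, interferon response, and p53 targets.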

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

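Tests chosen only after the results were seen are those of single probes, of macrophage markers, of exchanged labels and of chips. The tests of splits and of the chromosome 6 list were fixed before, and windows around Ltbr were not part of the plan. Of the 35 splits of the 7 arrays into 3 and 4, 2, counting the real one, gave at least as many genes as the real one. Chance is thus not excluded for the count of genes. The real split gave 12 genes and the highest other, with WT replicates 1 and 2 and KO replicate 3 against the rest, gave 196. The other 33 gave 0. A split that calls so many genes may point to a structure of the samples other than genotype. It only exchanges WT replicate 3 and KO replicate 3, however, and so shares much of the contrast of genotype. On the first principal component every WT sample (-29.0 to -2.6) lay below every KO sample (4.8 to 23.1). WT replicate 3 (-2.6) and KO replicate 3 (4.8) lay nearest each other. For lists, 11 of 35 splits, counting the real one, gave at least as many calls by camera as the real one. The real one gave 8 and the highest other gave 12, so chance is not excluded there either.

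No label named a factor behind the division of WT replicates 1 and 2 with KO replicate 3 from the others. In the order in which the series lists its samples, however, these 3 arrays alternated with the others. What that order reflects is not given in the sources used here. Exchanged labels of WT replicate 3 and KO replicate 3 are argued against by Ltbr, whose log2 value in WT replicate 3 lay 1.05 above the highest KO sample. Mug2 was at 12.34 in WT replicate 3 and 6.78 in KO replicate 3, each with its own group. A batch of chips or of tissue processing cannot be told apart from other causes, because the scanner table names 3 chips that the labels tie to no sample. Differences between animals, such as in the course of regeneration, may also be behind it and were not tested.

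The share called in the distal chromosome 6 list exceeded that elsewhere (one-sided Fisher's exact p = 0.00082). This rested on 2 genes, Mug2 and Ptms. With 1 array left out, Ptms kept its call only without KO replicate 3. Among the 50 genes on each side of Ltbr, 10 of 100 had an unadjusted p under 0.01, against 581 of 12363 elsewhere. The one-sided Fisher's exact p was 0.020, and 0.087 and 0.053 with 25 and 100 genes on each side. The called genes Mug2, Mug-ps1 and Ptms are among those 10, with Mug2 and Mug-ps1 near the edge of the window. The p of 0.020 thus in part repeats their calls and is not separate support. A chromosome segment carried along with the targeted Ltbr allele is a candidate explanation that the test of the list, which could have come out otherwise, leaves in place. Cd163, Gys2 and Slco1a4, named above for other lists, also lie within 100 tested genes of Ltbr. Whether such a segment bears on them was not tested. A sequence variant under a single probe is argued against by 1 further probe each, at -5.04 (SE 0.34) for Mug2 and -0.75 (SE 0.16) for Ptms. The remaining Mug2 probe, at -0.64, was above the floor on 3 arrays, none of them KO. The filter thus fixed its direction, and it does not bear on this. The median of these 3 other kept probes, all lower, was -0.75, which is the value of the Ptms probe alone. For Mug-ps1 the other probe, at -0.22, was below the floor, so that a variant cannot be told apart from a lower level. The paralog Mug1, chosen after its values were seen, differed by -0.21 (SE 0.19) at its brightest probe and by -0.64 (SE 0.23) at its other, dim one, and an effect of LTBR loss itself on these genes was not tested.

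Macrophage markers were higher in KO while several hepatocyte lists were lower, with the preset correlation only (adjusted p = 0.46 for the macrophage markers with an estimated correlation, and at least 0.27 for every list). A lower share of hepatocyte RNA would raise the markers of other cell types alike. Against this, endothelial and stellate markers were not higher in KO, with medians of -0.02 and -0.14. The macrophage score minus the mean of the endothelial and stellate scores was 0.49 higher in KO. The lowest KO sample lay at 0.06 and the highest WT sample at -0.24 (exact two-sided permutation p = 0.057, the smallest that this number of arrays allows). The macrophage list was picked because it was already higher, so the direction of this difference was largely set beforehand and adds little. Low macrophage RNA in WT replicate 3 alone may account for much of the list's median. The median went from 0.31 to 0.13 without that sample (0.56 without WT replicate 1). The score minus the others stayed 0.45 higher in KO without WT replicate 3, also the lowest WT sample for endothelial (-0.17) and stellate (-0.24) markers. This does not decide the question, because the macrophage score of WT replicate 1 (0.038) was above that of KO replicate 1 (0.032). The low score minus the others of WT replicate 1 came from the highest endothelial (0.15) and stellate (0.40) scores of any sample. The macrophage score of WT replicate 2 (-0.18) did lie below every KO sample. A change in macrophages with LTBR loss remains open.

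In KO, 9 of the 117 genes and lists examined had 1 sample far from the other 3, where about 5.85 are expected by chance, and the gap to the nearest sample is given as a share of the range. The NF-kB target list (0.928, KO replicate 4 high), the cholangiocyte marker list (0.904, KO replicate 4 high) and the cholesterol synthesis list (0.874, KO replicate 1 high) were of this kind. Among genes, KO replicate 4 stood apart for Cyp8b1 (0.864, low) and Fos (0.859, high). KO replicate 2 stood apart for Calr (0.844, low) and Socs3 (0.867, high). KO replicate 3 was low for Ccl5 (0.841), and KO replicate 1 was low for Pdgfa (0.860), whose 4 KO values all lay above WT.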

How the results depend on the processing

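The alternative leaving out both KO replicate 3 and WT replicate 3 was chosen after seeing the data. In it, genotype coincides with the division of WT replicates 1 and 2 with KO replicate 3 from the others. Its calls, among them those of Ltbr and Saa1 given below, thus cannot be assigned to genotype alone. The 12 genes called became 19 with no filter on dim probes, 1 with a stricter floor required on all 7 arrays (both changed together, 9468 tested), 22 with every kept probe tested and 7 with the mean of probes. They became 472 with array weights and 592 without both arrays, each time including all 12. Thresholds of adjusted p under 0.1 and of unadjusted p under 0.05 with 1.5-fold gave 99 and 818. Leaving out 1 sample gave 2 to 35 genes. The other settings, apart from the replicate block, gave 10 to 16. Mug2 passed in all 19 settings and Mug-ps1 in the 18 that tested it.

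The replicate block gave 3 genes, 2 of them among the 12, and 6 of the 8 lists. No WT sample shares the number of KO replicate 4, so the block takes that sample out of the comparison. Its log2 differences therefore equal those without KO replicate 4. Same-numbered samples deviated from their group means with correlations of -0.16, -0.04 and -0.26. No WT sample correlated best with the KO sample of its own number. The values thus gave no sign that the numbers pair the samples, though so few pairs cannot exclude it. The 8 lists became 0 with an estimated correlation, 1 with fry and 4 without both arrays, and 4 to 10 with 1 sample left out. Ltbr passed with array weights (-1.07) and without both arrays (-0.94), and otherwise lay between -1.22 and -0.55 without passing.

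Among genes that did not pass, some changed sign. With 1 sample left out, Socs3 ranged from -0.080 to 0.76, Saa1 from -0.048 to 0.97, Hgf from -0.48 to 0.20, Icam1 from -0.20 to 0.15, Foxm1 from -0.20 to 0.11, Ccne1 from -0.16 to 0.11 and Nfkb2 from -0.10 to 0.050. Saa1 passed in 1 of 19 settings, without both arrays (1.52, adjusted p = 0.0075, the highest being 0.996). Icam1 was 0.060 with array weights and 0.27 without both arrays. With the replicate block, Ccne1 was 0.11 and Nfkb2 0.0080. Over all genes named with a tested value besides Ltbr, and all settings, 1332 values kept direction and side of the threshold, 75 passed newly, 66 no longer passed and 19 changed sign. The cause of these changes was not tested, except that fewer genes or samples were tested where the filter or the samples changed. Slide as a block and filters on detection p were not run, because no label ties the scanner columns to samples and matching them by values was not tried. Median scaling moved nothing, since the deposited values were already normalized. Near the floor, differences are compressed, as for Mug-ps1 in KO.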

Other observations

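Apart from the macrophage markers and the adipocyte and mesothelium markers, lists of other cell types did not pass, by camera over 37 lists. Markers of B cells and plasma cells had 9 of 10 members above 0 and a median of 0.21 (adjusted p = 0.11), and stellate cell and fibroblast markers had 20 of 26 below 0 and a median of -0.14 (adjusted p = 0.12). Sinusoidal endothelial markers had a median of -0.02 (adjusted p = 0.49), monocyte and dendritic cell markers -0.08 (adjusted p = 0.62), neutrophil markers 0.13 (adjusted p = 0.97) and cholangiocyte markers 0.07 (adjusted p = 0.37). No member of these 6 lists passed adjusted over the list alone. Among T and NK cell markers (median -0.03, adjusted p = 0.80) the chemokine gene Ccl5 (0.59, SE 0.17) was higher adjusted over the list alone. Among erythroid markers (median -0.06, adjusted p = 0.30) the haem synthesis gene Alas2 (-0.78, SE 0.16) was lower adjusted over the list alone.

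No member passed adjusted over the list alone for pancreas markers (median -0.24, adjusted p = 0.41), lymphoid tissue chemokines (0.06, adjusted p = 0.97), heat shock proteins (0.10, adjusted p = 0.80) or NRF2 targets (-0.01, adjusted p = 0.97). The same held for MHC and antigen presentation (0.04, adjusted p = 0.97), circadian clock genes (-0.02, adjusted p = 0.83), male-biased liver genes (-0.06, adjusted p = 0.49) and female-biased liver genes (-0.14, adjusted p = 0.50). Median, mean and direction of the test differed in sign for 7 lists, namely G2/M and mitosis, p53 targets, growth factors, fatty acid oxidation, NRF2 targets, interferon response and MHC.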
